A study of Homo sapiens with 4 samples.

How the data were processed

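ZNF143, a zinc finger transcription factor that binds DNA and has been described at chromatin loop anchors, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in MCF-7, an oestrogen receptor positive human breast cancer cell line. The labels describe 4 libraries, 2 from cells given vehicle and 2 from cells given oestradiol (E2). Per the labels' protocols the cells were starved of oestrogen for 48 h and then given ethanol vehicle or 10 µM E2 for 45 min. The dose is printed as the labels give it.

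Of the processing before deposit, the submitters' processing notes name bcl2fastq 1.8.4, Bowtie2 2.0.5, MACS2 and the genome build hg19. Peaks were called with MACS version 2.0.10.20131216 at a q cutoff of 0.05, per the file headers. Each condition had 1 ChIP alignment file, whose name marks it as concatenated, and both conditions used the same concatenated input file, per the file headers. The header of the vehicle list names its alignment by a zero time point, and the list was taken as vehicle from the descriptions of its samples. The headers give a tag size of 51 bp, a fragment length of 154 bp, an effective genome size of 2700000000 bp and 1 tag kept per position and strand. Blacklist filtering and read trimming are not given in the sources used here.

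The deposited lists hold, per peak, the start and end, the summit, the pileup, the fold enrichment and −log10 of the p and q values, all as the authors' peak caller gave them. The pileup is a signal in extended fragments over the summit, counted after duplicate removal, per the file headers. The fold enrichment is a ratio of the pileup to the local background expected from the input, both with 1 added, per peak, in the authors' deposited lists. The headers of the columns of −log10 values in the deposited files were damaged, and the later one was read as −log10 q, since its lowest value lay just above that of the cutoff. These scores were used here to describe, rank or filter peaks within a list, and across the lists only for the calling level of list-only peaks.

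The depth behind the lists was read from the headers. The vehicle alignment held 127480210 tags, of which 20356318 (16.0%) were left after duplicate removal. The E2 alignment held 120801200 tags, of which 17037742 (14.1%) were left. The shared input held 63328931 tags, of which 31187734 were left. The E2 depth was thus 0.837 of the vehicle depth. Each list pools both replicates of its condition as far as the labels and headers tell, so the spread between replicates is unknown, no test between conditions across replicates was made. The probabilities given for single list-only peaks compare the 2 pooled lists, not the conditions. Shares are given with exact (Clopper-Pearson) 95% binomial intervals over peaks, which cover counting error only.

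Peaks of one list that overlapped a peak of the other by at least 1 bp were called shared, and the others list-only. The overlap given by chance was taken from 100 random circular shifts of one list within each chromosome (between the first and the last peak) and from shifts by 2, 10 and 100 kb. Each list was ranked by −log10 q, with ties broken by pileup and then by width, and divided into 10 groups of equal size. The ratio of median fold enrichments of shared and list-only peaks has a bootstrap interval from 1000 resamples of peaks. Peaks were counted by their summits in windows of 1 Mb and of 100 kb, and density per chromosome is over the 1 Mb windows that hold a peak in either list. The local background of a peak was recovered as (pileup + 1)/fold − 1 and divided by the lowest value of its list, which equals the genome-wide background that the header values give (1.16 fragments for vehicle and 0.972 for E2). Windows of raised background had at least 10 peaks and a median of at least 2 times the lowest in both lists.

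For each list-only peak the lowest pileup that would have been called in the other list was derived from its local background scaled by depth and from the lowest −log10 p of that list. A conditional binomial probability then gave the chance of staying under that level with equal binding and the observed depths, with a limit of 1e-06. This leaves out the minimum width that the caller asks of a peak and any difference in enrichment between the alignments. The overlap and distance functions were tested on simulated vehicle and E2 lists of 5000 pairs, in which all 3500 planted overlaps and 0 others were found. Of simulated pairs with equal rates, 0.64% had a conditional probability below 0.01. These pairs were not chosen by calling, so this does not check the test as applied to list-only peaks. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

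The comparisons of the lists, most alternatives and the rule for named items were set before the data were examined. The alternatives on local background and the tests named as such in the closing part were chosen afterwards. The rule asked for the 10 strongest peaks and the 10 strongest list-only peaks of each list, of which the text names some, together with members of gene lists at promoters. No hg19 genome or gene annotation was used here, and the gene table at hand is of assembly GRCh38.p14, whose coordinates do not apply to these peaks. The planned results on promoters, genes, gene lists and motifs were therefore not analysed here, and peaks are named by their hg19 coordinates (1-based) with no statement on the gene, exon or intron they lie in. The widest peaks, the chromosomes, the windows and the stretches of raised background were chosen after their values were seen. Counts over chromosomes cover chromosomes 1 to 22 and X.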

Results

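Binding of ZNF143 was mapped by ChIP-seq in MCF-7 breast cancer cells that had been starved of oestrogen for 48 h and then received vehicle or 10 µM E2, the main natural oestrogen, for 45 min. There were 2 libraries per condition, and the deposited data give 1 pooled peak list per condition, called against 1 shared input. After duplicate removal the vehicle list rested on 20356318 ChIP tags and the E2 list on 17037742. All scores per peak are those of the authors' peak caller. With 1 list per condition there is no replicate spread, and the intervals cover counting error only.

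ZNF143 peaks were called throughout the genome in both conditions. The vehicle list held 76802 peaks over 33.1 Mb and the E2 list 73798 peaks over 31.3 Mb. The median peak width was 290 bp in the vehicle list and 289 bp in the E2 list. Median fold enrichment over input was 7.37 (quartiles 5.09 and 13.9) in the vehicle list, and the upper quartile of −log10 q was 31.7. In the E2 list the median fold enrichment was 7.10 (quartiles 5.07 and 13.1) and the upper quartile of −log10 q was 26.1. A fold enrichment of at least 5 was reached by 78.3% of vehicle peaks and 76.4% of E2 peaks. The E2 list had both fewer peaks and fewer tags, 0.837 of the vehicle depth, so depth and treatment are not separated in the number of peaks.

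The question the design raises is which ZNF143 sites are present with and without oestrogen. Of the vehicle peaks, 58737 overlapped an E2 peak, which is 76.5% (95% interval 76.2 to 76.8%). Of the E2 peaks, 59423 overlapped a vehicle peak, which is 80.5% (80.2 to 80.8%). Random shifts of the other list within chromosomes gave 2.50% on average for vehicle peaks (highest of 100 shifts 2.98%) and 2.62% for E2 peaks (highest 3.15%). A shift by only 2 kb left an overlap of 9.97% for vehicle and 10.5% for E2 peaks, and a shift by 100 kb left 4.87% and 5.11%. The summits of shared peaks lay close together, at a median distance of 26 bp from the nearest E2 summit for vehicle peaks. For the 10000 strongest vehicle peaks, all shared, this distance was 10 bp, and 95.9% lay within 50 bp. Under summits within 100 bp in place of any overlap, the shared share was 66.3% of vehicle and 69.0% of E2 peaks.

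The strongest sites were present in both conditions. All of the 500, 1000, 5000 and 10000 strongest peaks of either list overlapped a peak of the other (lower 95% limit for 10000 peaks, 99.96%). An overlap with a peak among the same number of strongest peaks of the other list was found for 95.8% of the 5000 strongest peaks of either list, and for 92.5% of the 10000 strongest vehicle and 92.6% of the 10000 strongest E2 peaks. This was not read for the 500 and 1000 strongest, whose order rests largely on peak width among tied scores. The strongest list-only peak ranked 20262 in the vehicle list and 13712 in the E2 list. The shared share rose with strength within each list. It was 35.6% (34.5 to 36.6%) in the weakest 10% of the vehicle list, 79.4% (78.5 to 80.3%) in the group of rank 5 from below and 99.8% in that of rank 8. In the E2 list the same groups had 41.1% (39.95 to 42.21%), 85.2% (84.4 to 86.0%) and 99.8% shared.

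**Figure D1:**
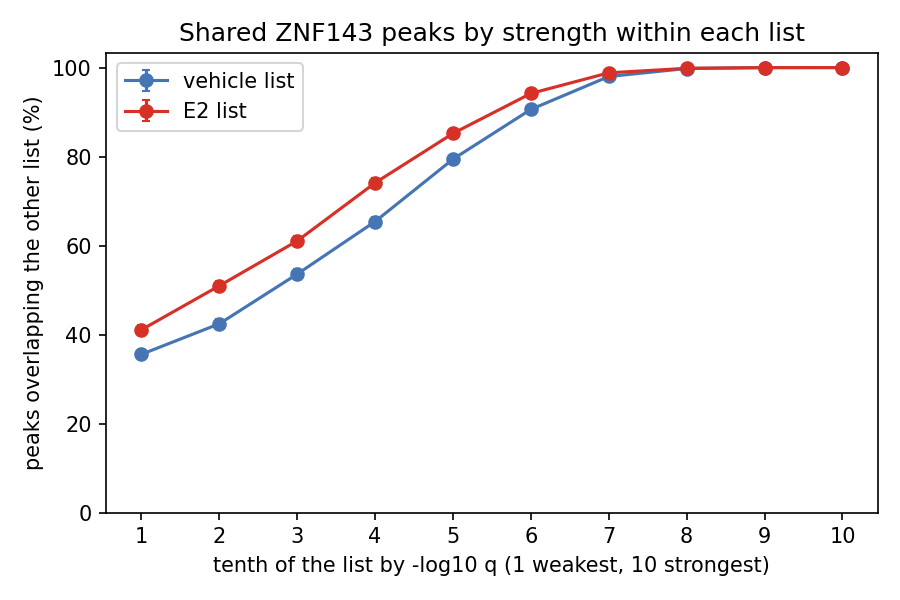
Share of ZNF143 peaks that overlap a peak of the other list (%, y axis) for 10 groups of equal size by −log10 q within each list (x axis, 1 weakest, 10 strongest); points are shares of the vehicle and E2 lists and bars, mostly hidden by the points, are exact 95% binomial intervals. The share rises from 35.6% to 100% of vehicle peaks and from 41.1% to 100% of E2 peaks.

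Among the strongest places was a peak on chromosome 7 at 150776642 to 150781242 (hg19), 4601 bp wide, which ranked first in both lists. On chromosome 11, peaks at 64608953 to 64613128 and 64036017 to 64039721 were among the 4 strongest of both lists. Other strong vehicle peaks lay on chromosome 19 at 4064326 to 4067884, on chromosome 16 at 30100880 to 30104433 and on chromosome 17 at 7121577 to 7125085, and each had a counterpart among the 10 strongest E2 peaks. Each of the peaks named in this paragraph had a pileup of 308 fragments and a fold enrichment of 143 in the vehicle list. These are top values of the scale, since 850 vehicle peaks and 726 E2 peaks were tied at the highest −log10 q, and the order among them rests on pileup and then peak width.

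List-only peaks were weak and narrow. The 18065 vehicle-only peaks had a median fold enrichment of 4.82, against 9.25 for shared vehicle peaks, a ratio of 1.92 (bootstrap 95% interval 1.88 to 1.93). The 14375 E2-only peaks had a median of 4.56, against 8.60 for shared E2 peaks, a ratio of 1.88 (1.86 to 1.89). Their median width was 187 bp in the vehicle list and 181 bp in the E2 list, against 345 and 332 bp for shared peaks. A wider peak meets the rule of 1 bp of overlap more easily, so this contrast can follow in part from the rule. Whether binding differs between the conditions was not tested across replicates, as each condition had 1 list.

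The strongest E2-only peak lay on chromosome 8 at 98776553 to 98776877, at a local background of 2.81 times the lowest. It had a pileup of 48, a fold enrichment of 13.1 and a −log10 q of 39.7. The next lay on chromosome 10 at 6196574 to 6196939, with a pileup of 33 and a fold enrichment of 16.2, and on chromosome 6 at 134438528 to 134438840, with a pileup of 32 and a fold enrichment of 16.4. The nearest vehicle peaks were 10488, 6828 and 2495 bp away. An E2-only peak on chromosome 9 at 130789043 to 130789499, with a fold enrichment of 14.7, lay only 52 bp from a vehicle peak. The strongest vehicle-only peak lay on chromosome 8 at 49288640 to 49288948, with a pileup of 31, a fold enrichment of 13.9 and a −log10 q of 29.6, and the nearest E2 peak was 3902 bp away. Vehicle-only peaks on chromosome 7 at 35067653 to 35067904 and at 39927897 to 39928270 had fold enrichments of 9.36 and 12.2. Their local backgrounds were 3.37 and 1.69 times the lowest. A vehicle-only peak on chromosome 12 at 44069035 to 44069548 had a fold enrichment of 13.6 and lay 82981 bp from any E2 peak.

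ZNF143 peaks were spread unevenly over the chromosomes. Chromosome 19, known for its high gene density, had 71.2 vehicle peaks and 70.7 E2 peaks per 1 Mb window holding a peak. Chromosomes 17 and 16 followed with 52.1 and 52.0 vehicle peaks per window. Chromosome 13 had 12.3, chromosome 18 12.4 and chromosome 4 13.4. The shared share of vehicle peaks ran from 73.8% (72.2 to 75.4%) on chromosome 14 to 81.1% (79.8 to 82.3%) on chromosome 19. The number of E2 peaks over that of vehicle peaks ran from 0.917 on chromosome 3 and 0.927 on chromosome 15 to 1.00 on chromosome 18 and 1.02 on chromosome 22.

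**Figure D2:**
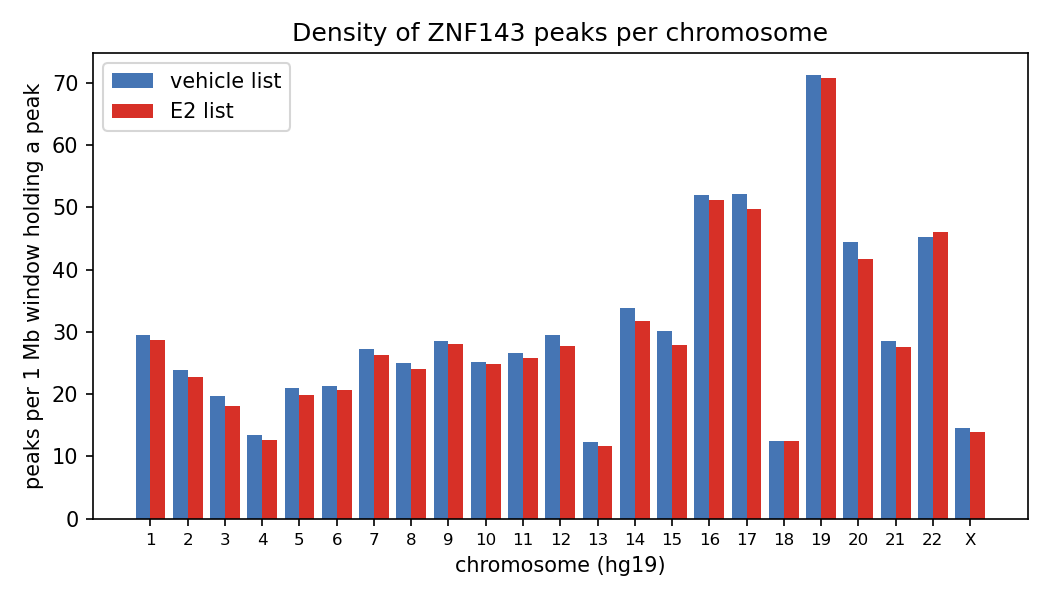
ZNF143 peaks per 1 Mb window that holds a peak in either list (y axis) for chromosomes 1 to 22 and X (x axis, hg19); bars are the vehicle and E2 lists. Chromosome 19 stands highest with 71.2 and 70.7 peaks per window, and chromosome 13 lowest among vehicle bars with 12.3.

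Single regions were far denser in peaks than the average window of their chromosomes. The median 1 Mb window held 18 vehicle peaks and 17 E2 peaks, and 85 windows with at least 100 vehicle peaks held 14.4% of all vehicle peaks on these chromosomes. By vehicle peaks the fullest window was 105 to 106 Mb of chromosome 14, with 229 vehicle and 227 E2 peaks. Next came 47 to 48 Mb of chromosome 8 with 214 and 195, 85 to 86 Mb of chromosome 16 with 213 and 201, 89 to 90 Mb of chromosome 16 with 191 and 168, and 49 to 50 Mb of chromosome 19 with 180 vehicle and 184 E2 peaks.

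The widest peaks lay side by side on chromosome 1. In the vehicle list 3 peaks of 10787 to 15010 bp covered 99.4% of the 38.6 kb from 228744053 to 228782667, with fold enrichments of 17.7 to 24.6. In the E2 list 3 peaks of 10459 to 15576 bp covered 99.5% of 228744019 to 228782676, with fold enrichments of 22.9 to 28.9. The next widest peak of either list was on chromosome 19, from 49012078 to 49017887 in the vehicle list (5810 bp) and from 49011941 to 49017792 in the E2 list (5852 bp), with its summit at 49017243 in both.

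The heights of the strongest peaks met an upper limit. The highest pileup was 308 in both lists, which is 2 times the fragment length of 154 bp, and 1894 vehicle and 1636 E2 peaks stood at exactly this value. From 300 to 308 there were 2361 vehicle and 2102 E2 peaks, against 197 and 182 from 291 to 299. Peaks at this value cannot be ranked by height within a list.

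**Figure D3:**
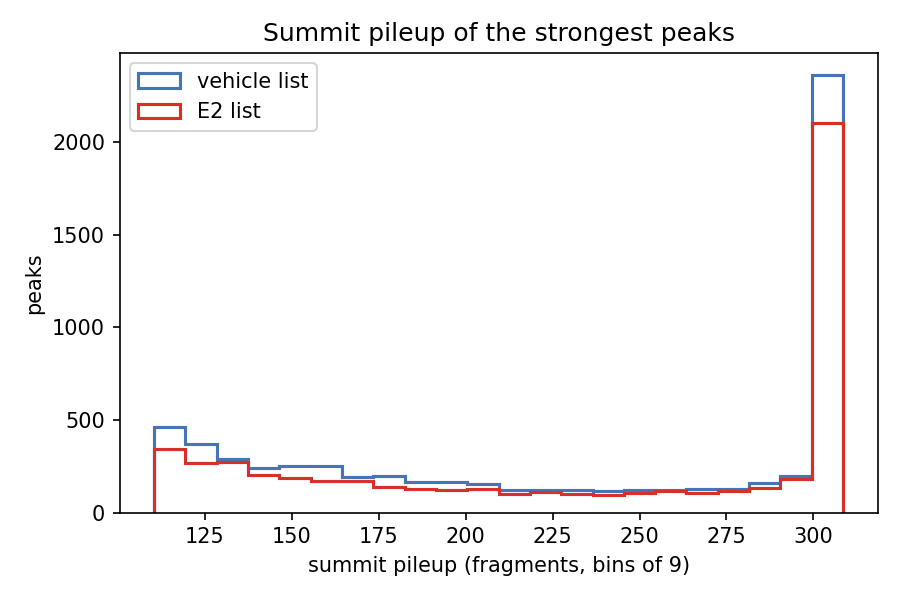
Number of ZNF143 peaks (y axis) by summit pileup in fragments (x axis, bins of 9) for the upper part of the range, with 1 line per list. The last bin, 300 to 308, holds 2361 vehicle and 2102 E2 peaks against 197 and 182 in the bin before.

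The local input background of the peaks was near the lowest value over most of the genome and raised over long stretches. Of the 1997 windows of 1 Mb with at least 10 peaks in both lists, 72 had a median background of at least 2 times the lowest in both. The 12 windows from 55 to 67 Mb of chromosome 17 held 633 vehicle peaks with a median background of 3.20 times the lowest, and the window from 59 to 60 Mb reached 18.3. On chromosome 20, the stretch from 45 to 51 Mb had a median of 4.42 over 573 vehicle peaks, and the window from 52 to 53 Mb reached 25.3. On chromosome 3, the 65 vehicle peaks from 62 to 65 Mb had a median of 10.5. The highest vehicle medians lay outside long stretches, at 90.5 from 42 to 43 Mb of chromosome 10. From 92 to 93 Mb of chromosome 2 the median was 57.9, and from 51 to 52 Mb of chromosome 11 it was 56.8. Vehicle peaks in raised windows had a median pileup of 33 and a median fold enrichment of 5.95, against 17 and 7.40 in other windows. E2 peaks had 29 and 6.01 in raised windows, against 15 and 7.10. These contrasts follow in part from choosing windows by background, which divides the fold enrichment and raises the pileup needed for a call. Of the vehicle peaks in raised windows 78.6% (77.2 to 80.0%) were shared, against 76.4% (76.0 to 76.7%) elsewhere.

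**Figure D4:**
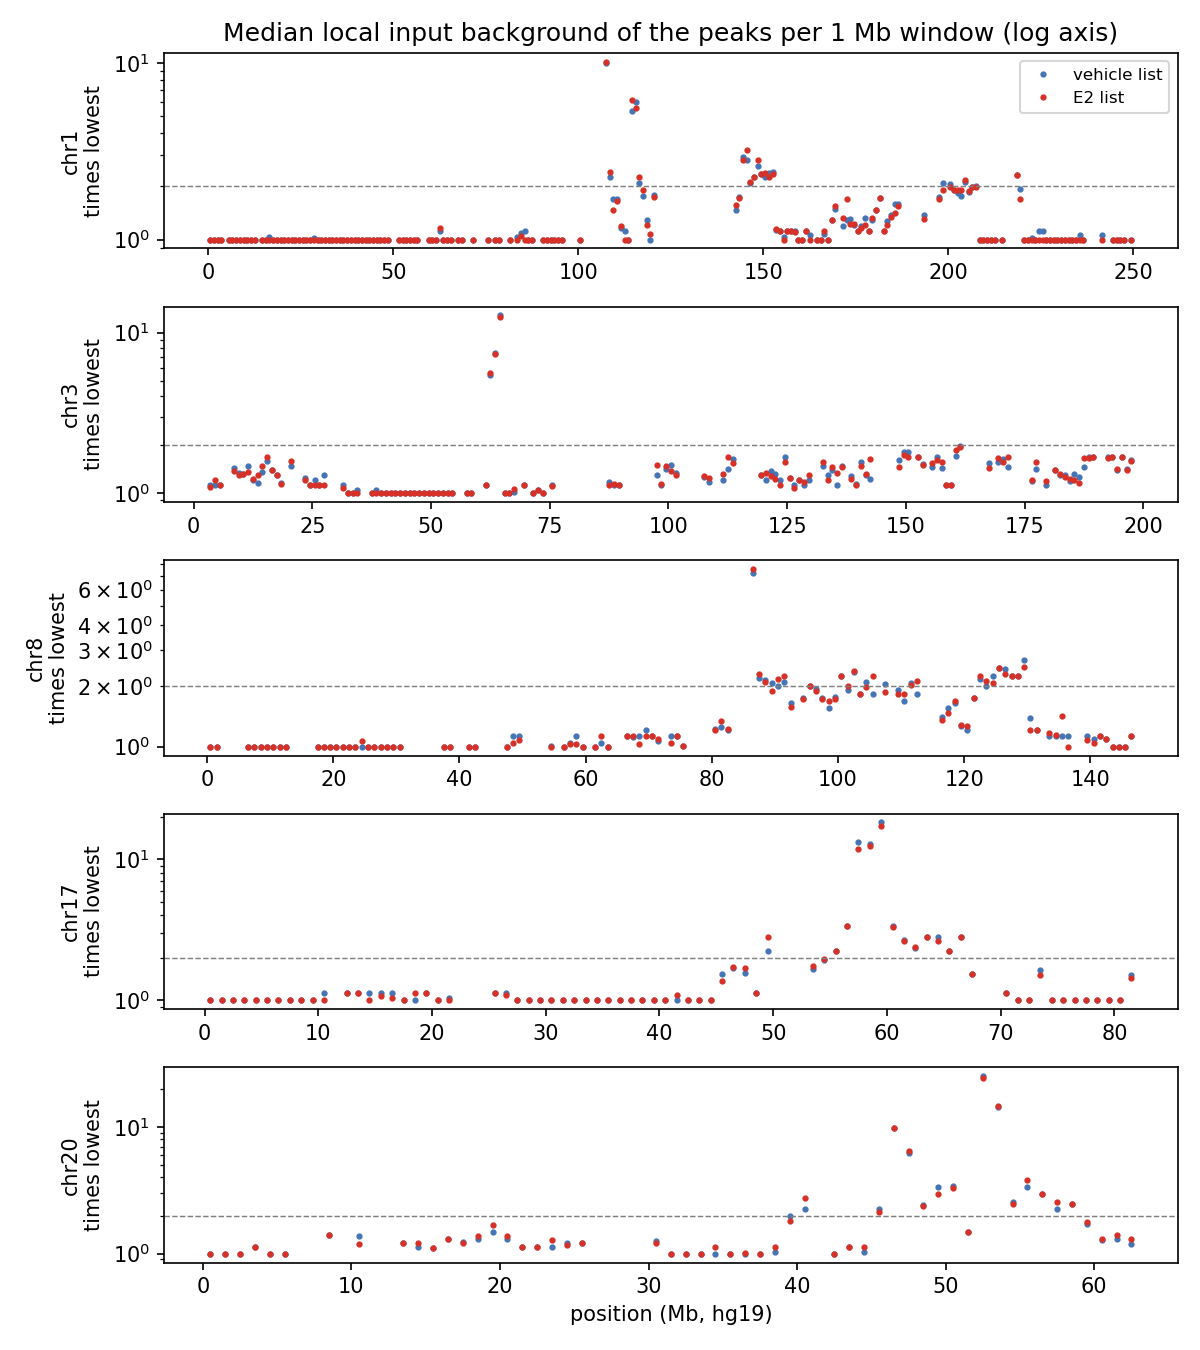
Median local input background of the ZNF143 peaks per 1 Mb window, as a multiple of the lowest value of the list (y axis, log scale), along chromosomes 1, 3, 8, 17 and 20 (x axis, Mb, hg19), for windows with at least 10 peaks in both lists; points are the vehicle and E2 lists and the dashed line stands at 2. The window from 52 to 53 Mb of chromosome 20 reaches 25.3 and that from 59 to 60 Mb of chromosome 17 reaches 18.3 in the vehicle list.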

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

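The tests of calling near the threshold, of the pileup limit and of the raised background were chosen after those results were seen, and the tests of the strong list-only peaks before. The local background reflects the shared input, on which peak calling rests but which is not the ZNF143 signal itself, and stretches of at least 3 neighbouring windows stood out in it. In the vehicle list the median, as a multiple of the lowest value, was 2.81 from 114 to 117 Mb and 2.34 from 144 to 153 Mb of chromosome 1, and 10.5 from 62 to 65 Mb of chromosome 3. It was 6.22 from 86 to 89 Mb and 2.34 from 124 to 130 Mb of chromosome 8, and 3.20 from 55 to 67 Mb of chromosome 17. On chromosome 20 it was 4.42 from 45 to 51 Mb and 3.07 from 52 to 59 Mb. The value from 86 to 89 Mb of chromosome 8 rested largely on the window from 86 to 87 Mb. That window held 84 of the 119 vehicle peaks at a median of 7.29, against 2.20 and 2.14 in the windows after it.

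Of the 72 windows of raised background, 55 lay next to another one, while the highest of 1000 random draws was 19. This argues against causes at isolated places for the windows as a set. It cannot exclude repeats or collapsed sequences, which can themselves lie in neighbouring windows. Windows of very high background may be of that kind, such as 42 to 43 Mb of chromosome 10 with a median of 90.5 times the lowest. Another is 92 to 93 Mb of chromosome 2, with 57.9, which counts among the neighbouring windows. A gain in copies of long stretches in the input DNA stays open as a candidate explanation. In 68.1% of the windows at least 90% of the peaks of both lists lay above 1.5 times the lowest, but this share largely follows from choosing the windows by their median background and so decides nothing. MCF-7 is known to carry extra copies of parts of chromosomes 1, 17 and 20. This was not tested against the stretches, and it does not cover those on chromosomes 3 and 8, whose medians reached 10.5 and 6.22. Copy number itself was not measured, and as both conditions share the input, agreement of the lists here is no replication.

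At least 95.1% of the list-only peaks of either list lay in the weaker 50% of their own list by −log10 q. That part reaches a −log10 q of 11.3 in the vehicle and 9.81 in the E2 list, far above the lowest values of 1.32 and 1.31. The lower quartile of list-only peaks was 3.83 in the vehicle and 2.94 in the E2 list. The share thus shows that list-only peaks were weak, but cannot show that they lay near the calling threshold. A conditional binomial probability below 1e-06 of staying under the calling level of the other list was found for 2 list-only peaks, both E2-only. They lay on chromosome 8 at 98776553 to 98776877 (5.88e-09) and on chromosome 10 at 6196574 to 6196939 (5.37e-07). Of vehicle-only peaks, 0 passed, with a lowest value of 4.70e-05. E2-only peaks were set against the deeper vehicle list, where a given pileup gives a lower probability, so 2 against 0 shows no lean. Most list-only peaks were too low to reach the limit: their median pileup was 11 (vehicle) and 9 (E2), against 48 and 33 here. The count thus cannot show that noise accounts for the others. That count of 2 lies between the bounds set beforehand, at most 1 and more than 10, so by that rule noise as the whole cause stays undecided. For a site fixed in advance, equal binding gives a chance of at most 1e-06 of such a value. These 2 sites were instead picked as called in 1 list, at its own summit, and missing in the other. The bound therefore does not hold for them, and their values do not decide on counting noise as modelled. The model leaves out the minimum width and differences in enrichment, and the peak on chromosome 8 lay at a local background of 2.81 times the lowest. A shifted or split peak is argued against for these 2 peaks, as 0% of them lay within 1000 bp of a vehicle peak, but it stays open for others, since 27.8% of all vehicle-only and 30.0% of all E2-only peaks lay within 1000 bp of a peak of the other list. An effect of E2 cannot be told apart from a difference between libraries for these 2 peaks, since each condition has 1 pooled list.

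The gathering of summits at a pileup of 308 is consistent with the setting of 1 tag per position and strand, which allows 2 tags per base of the fragment length. The lower of the ratios between the last 9 values and the 9 before was 11.5, and the limit was the same in both lists although the E2 depth was 0.837 of the vehicle depth. No biological explanation was tested for this pattern.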

How the results depend on the processing

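No paired analysis was possible because each list pools both replicates of its condition, and for the same reason leaving out a replicate was not possible. The alternatives on promoter windows, gene sets, random gene lists and motifs were not run, as no hg19 annotation or genome was used here. The settings on local background and on windows of raised background were chosen after seeing the data. Of 46 alternative values, 23 stayed within the interval of the main value (for numbers of peaks, within 1.5 times) and 23 moved.

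The shared share of vehicle and E2 peaks was 68.1% and 70.9% with a reciprocal overlap of 50%, and 66.3% and 69.0% with summits within 100 bp. With a −log10 q of at least 5 in the counted list it was 84.6% and 91.2%, and with that limit in both lists 75.7% and 86.8%. With equal numbers of peaks it was 78.3% and 79.4%, where matched lengths bring the values together by construction. Among peaks with a background of at most 2 times the lowest it was 74.5% and 78.2%. The cause of these shifts was not tested, beyond the stricter rule for overlap or the smaller number of peaks that each setting sets by construction.

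With summits within 100 bp, the 500, 1000, 5000 and 10000 strongest vehicle peaks were shared at 98.6%, 98.9%, 99.1% and 98.5%, and the E2 peaks at 98.0%, 98.7%, 99.02% and 98.4%. Ranking by fold enrichment left all of them at 100%. The ratio of medians of shared over list-only peaks was 1.96 in the vehicle list with reciprocal overlap, and 3.21 (vehicle) and 3.10 (E2) when −log10 q replaced fold enrichment. The depth, 20356318 and 17037742 tags, limits what can be said of weak peaks: absence from a list is no evidence of absent binding.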

Other observations

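The following places were chosen after their values were seen. On chromosome 8, from 47000001 to 47400000, 4 neighbouring windows of 100 kb held 202 vehicle peaks and 183 E2 peaks. The 1 Mb before held 4 vehicle peaks and the 1 Mb after 23. How much of that sequence is assembled and can be mapped was not examined, so no drop in binding is read from these counts. The windows from 47100001 and from 47000001 were the fullest of all 20363 windows of 100 kb with a vehicle peak, with 71 and 63 peaks against a median of 2. Summits of neighbouring vehicle peaks in the cluster lay a median of 1052 bp apart. Their median fold enrichment was 7.40 in the vehicle list, against 7.37 for the whole list, and 6.59 in the E2 list, against 7.10. Their median pileup was 16 against 18 in the vehicle list and 12 against 15 in the E2 list. Of the cluster, 79.2% (73.0 to 84.6%) of vehicle peaks and 89.6% (84.3 to 93.6%) of E2 peaks were shared. Peaks this dense overlap by chance more often than the genome-wide shifts show, and the chance overlap within the cluster was not measured. The local background was above 1.5 times the lowest at 9 of the 202 vehicle peaks.

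Other windows of 100 kb with many peaks lay on chromosome 19 from 36700001 (53 vehicle and 45 E2 peaks), on chromosome 16 from 88800001 (43 and 48) and on chromosome X from 114900001 (41 and 35). The run of wide peaks on chromosome 1 from 228744053 to 228782667 had pileups of only 60 to 64 in the vehicle list, far from the limit of 308, over nearly the whole of 38.6 kb. The array of 5S ribosomal RNA genes is known to lie on the distal long arm of this chromosome, and whether these peaks lie in it was not tested, as no hg19 annotation was used here.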
